A study of Mus musculus with 36 samples.

How the data were processed

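RNA was measured in whole bladders of female mice of 1 genotype, CaMKII-Cre; Bmal1fx/fx, which the labels describe as a conditional knockout of Bmal1 (gene symbol Arntl) in the central nervous system. The mice had been kept in constant darkness for 2 days (ShortDD) or 8 weeks (LongDD), and each bladder carried a time label of 4, 8, 12, 16, 20 or 24. The unit of the time label is not given in the sources used here, and it was taken as hours. Each of the 12 groups held 3 libraries, so each arm held 18 libraries and the series 36. No other genotype was part of the series. Per the labels, 500 ng of total RNA was depleted of ribosomal RNA and made into directional libraries.

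The per-sample tables deposited by the authors hold read counts for 49585 genes, which are whole numbers per gene (raw counts of reads in exons, without normalization), and the submitters' processing notes name the genome build mm10. The aligner, the counting tool and the strand setting are not given in the sources used here. The expression value was never above the total exon reads of the same table and made up 86.3% to 89.0% of them. The same tables also give unique and total exon reads, unique and total intron reads and total gene reads. The 2 tables for the whole series, 1 per arm, hold normalized signal made by the authors. Their columns all held the same sorted values, within 0.001 of the mean of the arm's sorted counts, which is quantile normalization over the 18 libraries of an arm. These tables were used for 1 alternative.

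Totals ran from 9083644 to 12344669 counts in ShortDD and from 10421091 to 14121050 in LongDD. The chi-square per degree of freedom between replicate pairs, over genes with at least 10 counts in the pair, ran from 5.36 to 46.3, so the spread between animals was far above counting error. Intron reads made up 20.7% to 38.8% of gene reads and mitochondrial genes 1.06% to 1.65% of counts.

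Rhythms were fitted in each arm separately with a cosine and a sine of period 24 in edgeR 4.0.16 (R 4.3.3), with TMM scaling, the filterByExpr filter on the 6 groups and a robust quasi-likelihood F test of both terms (2 degrees of freedom). The range of a gene is the peak-to-trough difference of the fitted curve on the log2 scale. Standard errors of ranges and peaks came from a least squares cosinor on log2 CPM (counts divided by the scaled library size) with a prior count of 2. A second edgeR model of all 36 libraries held the arm and a cosinor within each arm. Its arm term tested the mean level and its interaction terms tested a difference in rhythm. All p-values across genes were adjusted by the Benjamini-Hochberg (BH) method, and a gene passed at an adjusted p under 0.05. Overlaps were tested with Fisher's exact test (one-sided). It takes genes as independent, which they are not where whole libraries differ, so its p-values can be too small.

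Before the data were examined, 24 gene lists were fixed: core clock, clock output, glucocorticoid response, heat shock and cold-inducible, unfolded protein response, immediate early, urothelium, smooth muscle contraction, bladder sensing and contraction signalling, fibroblast and extracellular matrix, cell cycle, interferon response, inflammatory, cholesterol synthesis, fatty acid and PPAR metabolism, oxidative phosphorylation (nuclear), skeletal muscle markers, adipocyte markers, T and B cell markers, myeloid markers, endothelial markers, nerve and glia markers, blood markers and female reproductive tract markers. Their members were counted over all genes tested and adjusted over the list alone. Enrichment among passing genes was tested with Fisher's exact test and mean level with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, each with BH adjustment over the 24 lists. The difference in mean range of the 25 core clock and clock output genes between arms was tested by permuting arm labels within time labels after centring each gene in each arm (100000 draws, two-sided).

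Genes were named by a rule fixed at the same time. It took every core clock and clock output gene, then per arm the 10 further passing genes with the largest range and a mean of at least 1 CPM. For the rhythm difference it took the 10 genes with the largest F. For the level it took the 10 highest and 10 lowest passing genes with the same sign at 5 or more of the 6 time labels. It added up to 4 members per list with the smallest p in the comparison described. Gene models without a standard symbol were counted but not named, and 2 list members are not reported here, although the counts and tests of their lists include them.

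The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom without and with sample quality weights, RLE factors or library totals in place of TMM, no filter or a mean of at least 1 CPM, the replicate number as a block, and each library left out in turn. They also held an adjusted p under 0.01, the time label as a factor (5 degrees of freedom), an added harmonic of period 12 (4 degrees of freedom), periods 22 and 26, a range of at least 1, the authors' normalized tables (log2 of the value plus 1, mean of at least 10), and for the level a fold of at least 1.5, group means and an arm term plus a time factor. Chosen after seeing the data were total or unique exon reads as input, a replicate block nested in arm, and the omission of sets of libraries that stood apart on principal components. For each count, 100 assignments of the libraries, the real one included, were fitted with a fixed seed.

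The fits were also tested on simulated data with the spread of each gene within groups, in which 200 genes carried a known change per comparison. Genes were drawn independently, so differences shared by whole libraries were absent, and the shares recovered need not hold for the real counts. At a range of 1, 68.7% of the changed genes were recovered in ShortDD and 71.6% in LongDD, and at a range of 0.5 the shares were 28.4% and 41.8%. For the level, 83.6% were recovered at a log2 fold of 0.50, and for a rhythm present in 1 arm alone 68.7% at a range of 1. Other calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and matplotlib 3.10.9 drew the plots.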

Results

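Transcripts were counted in 36 whole-bladder libraries from female mice that carried floxed Bmal1 with a CaMKII-Cre driver. The title of the series concerns a bladder rhythm without the central clock. The libraries fell into 12 groups of 3, namely 6 time labels (4, 8, 12, 16, 20 and 24, taken as hours) after 2 days of constant darkness (ShortDD) and the same 6 after 8 weeks (LongDD). The total per library was 9083644 to 12344669 counts in ShortDD (n = 18) and 10421091 to 14121050 in LongDD (n = 18). Between 17405 and 17921 genes had at least 1 count in a library. No library of another genotype was part of the series, so no value could be set against an unmodified mouse.

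Arntl (ENSMUSG00000055116, also called Bmal1, the transcription factor that was floxed) lies on chromosome 7 from 113207465 to 113314126 in mm10. Its transcript was present in every bladder library, a tissue outside the central nervous system that the driver was chosen for. Counts scaled to library size (CPM) ran from 7.20 to 30.35 CPM in ShortDD and from 12.11 to 28.95 CPM in LongDD. The counts cover the whole gene, so they do not tell an intact from a recombined transcript. In ShortDD the group mean was lowest at label 8 (10.8 CPM ± 3.17, SD, n = 3) and highest at label 24 (28.6 CPM ± 2.63, SD, n = 3). In LongDD it was lowest at label 8 (13.4 CPM ± 1.42, SD, n = 3) and highest at label 20 (22.2 CPM ± 3.24, SD, n = 3).

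The first comparison asked which bladder transcripts followed the time label after 2 days of darkness. Clock genes rose and fell over a wide range. Nr1d1, which encodes the repressor REV-ERB alpha, had a fitted peak-to-trough range of 2.35 ± 0.31 (log2, SE, n = 18) with its peak at 5.1 h, and its group means ran from 122 CPM ± 13.9 (SD, n = 3) at label 4 to 27.6 CPM ± 8.53 (SD, n = 3) at label 16. Dbp, a PAR bZIP transcription factor driven by the clock, had a range of 2.40 ± 0.35 with its peak at 7.0 h. Arntl peaked on the other side of the cycle, at 20.5 h, with a range of 1.48 ± 0.17. The period genes Per2 and Per3 had ranges of 1.36 ± 0.20 and 1.36 ± 0.21 and peaked at 10.8 h and 10.2 h.

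In the edgeR test with BH adjustment, 19 of 14528 genes passed in ShortDD, and 1905 genes (13.1%) had an unadjusted p under 0.05. In the core clock list 5 of 12 members passed over all genes, namely Arntl (adjusted p = 0.000752), Nr1d2 (0.00138), Nr1d1 (0.00139), Per2 (0.00321) and Per3 (0.00885), and 8 passed when adjusted over the list alone. The other 3 of those 8 were Clock, the partner of Arntl, with a range of 0.29, its paralog Npas2 with 0.71 and the repressor Cry1 with 0.51. Per1 (0.99), Cry2 (0.33) and Rora (0.07) passed neither. In the clock output list 5 of 13 members passed over all genes, namely Bhlhe41 (adjusted p = 0.000719), Dbp (0.00262), Tef (0.00311), Nfil3 (0.0293) and Por (0.034), and 13 of 13 passed when adjusted over the list alone. The other members had ranges of 3.00 (Ciart), 1.58 (Usp2), 0.92 (Hlf), 0.81 (Bhlhe40), 0.75 (Tsc22d3), 0.61 (Wee1), 0.55 (Coq10b) and 0.47 (Tspan4). Both lists were enriched among the 19 genes (Fisher's exact test, adjusted p = 3.31e-11 each).

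**Figure D1:**
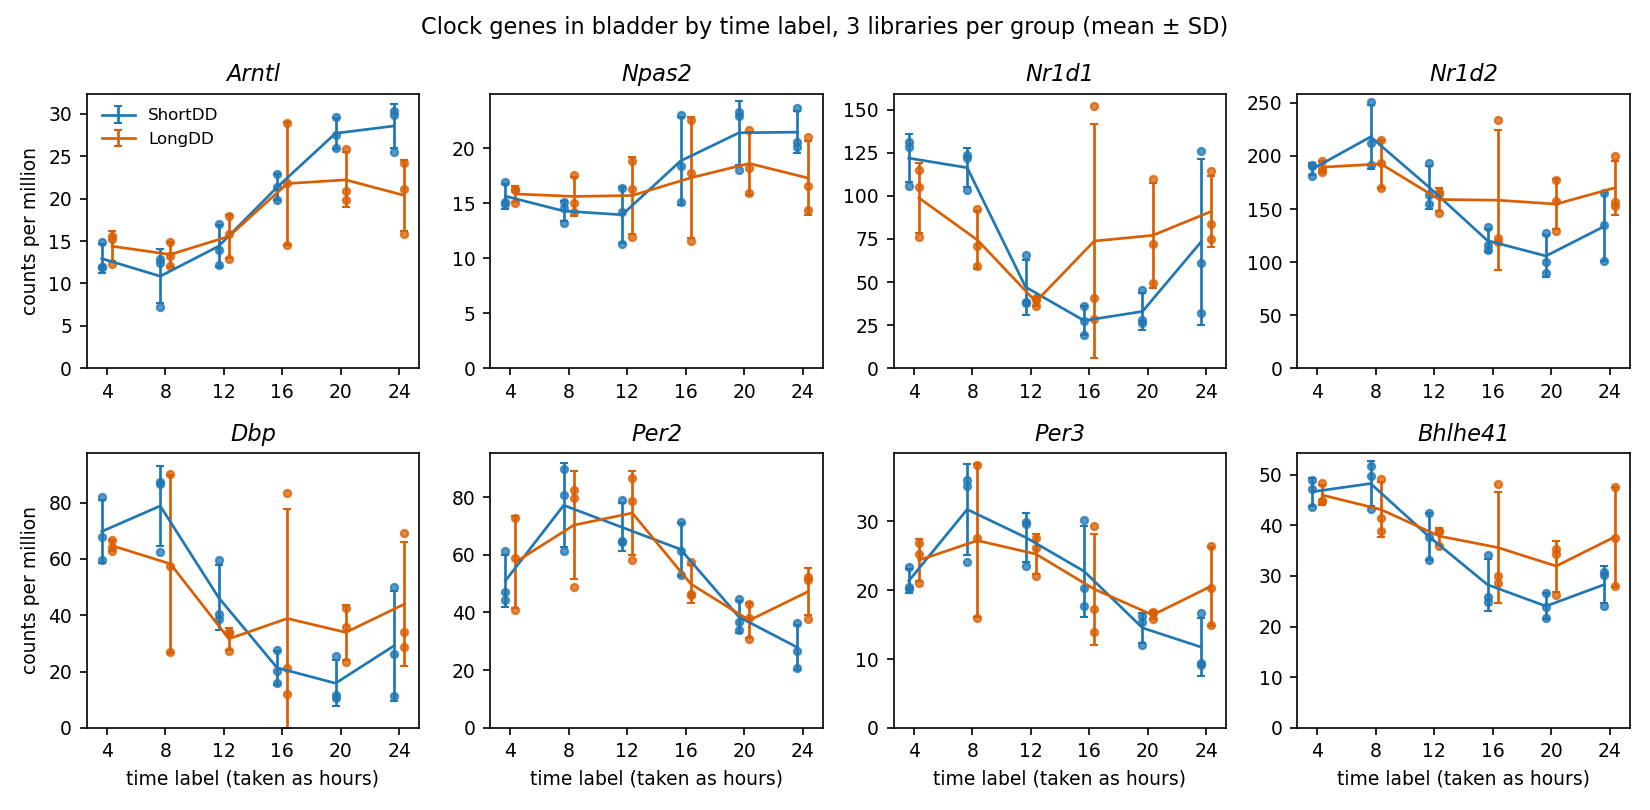
Normalised counts (CPM) of 8 clock genes by time label. Points are libraries (3 per group), lines join group means and bars are SD. Nr1d1 in ShortDD falls from a mean of 122 CPM at label 4 to 27.6 CPM at label 16, and 1 LongDD library at label 16 lies at 152 CPM.

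Outside the clock lists, Rnf144a, a ubiquitin ligase, had a range of 0.89 ± 0.10 and peaked at 0.2 h (adjusted p = 0.00139). Fmo1, a flavin-containing monooxygenase, had a range of 1.12 ± 0.17 and peaked at 13.7 h (0.0045). The extracellular protease Adamts4 had a range of 1.64 with its peak at 21.0 h (0.0399). Mtus2 (range 0.83, adjusted p = 0.0146) and Pitpnm2 (0.62, adjusted p = 0.034) peaked at 14.3 h and 12.7 h. The immediate early gene Junb (0.54, adjusted p = 0.0311) peaked at 4.3 h, Negr1 (0.48, adjusted p = 0.044) at 20.5 h and Dpt, which encodes the matrix protein dermatopontin, at 22.3 h (0.67, adjusted p = 0.044). The last of the 19, Zfp385c, lay below the minimum of the naming rule (mean 0.656 CPM) and is named because it completes the set.

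In the other lists of ShortDD, Junb was the only member that passed over all genes. Adjusted over the list alone, 9 of 15 myeloid markers, 6 of 6 blood markers, 2 of 17 immediate early genes (Junb and Ier2) and 2 of 18 fibroblast and extracellular matrix genes (Eln and Lum) passed. So did 1 gene each of fatty acid and PPAR metabolism (Srebf1), skeletal muscle markers (Myl1) and adipocyte markers (Fabp4). No member passed in glucocorticoid response, heat shock and cold-inducible, unfolded protein response, urothelium, smooth muscle contraction, bladder sensing and contraction signalling, cell cycle, interferon response, inflammatory, cholesterol synthesis, oxidative phosphorylation (nuclear), T and B cell markers, endothelial markers, nerve and glia markers or female reproductive tract markers (edgeR). At an unadjusted p under 0.05 these lists had, in the same order, 1, 1, 4, 8, 0, 1, 12, 8, 0, 5, 5, 0, 2, 2 and 0 members.

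Myeloid, cell cycle and interferon transcripts stood out in single bladders. Library 2 of ShortDD label 20 had a mean log2 CPM above the mean of all libraries by 2.42 for cell cycle, 2.27 for interferon response, 1.67 for T and B cell markers and 1.12 for myeloid markers. Libraries 2 and 3 of ShortDD label 24 lay above it by 0.56 and 0.75 for myeloid markers. Without these 3 libraries, a choice made after seeing the data, 0 of 15 myeloid markers, 0 of 20 cell cycle genes and 0 of 18 interferon response genes had an unadjusted p under 0.05 in ShortDD, against 11, 12 and 8 with them (edgeR), whereas 7 of 8 blood markers did, against 6 of 6. Skeletal muscle markers lay above the mean by 1.85 and 1.91 in library 3 of labels 4 and 8.

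The count of 19 in ShortDD fell to 9 without those 3 libraries and was 123 with DESeq2 in place of edgeR. Arntl, Bhlhe41, Dbp, Nr1d1, Nr1d2 and Tef passed in each of 36 alternatives, whereas Adamts4, Junb, Negr1, Dpt, Pitpnm2, Por and Zfp385c lost their place in 17 to 24, Nfil3 in 11 and Mtus2 in 7. These losses go by the adjusted p alone, so falling short of a range of at least 1 was not counted.

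**Figure D2:**
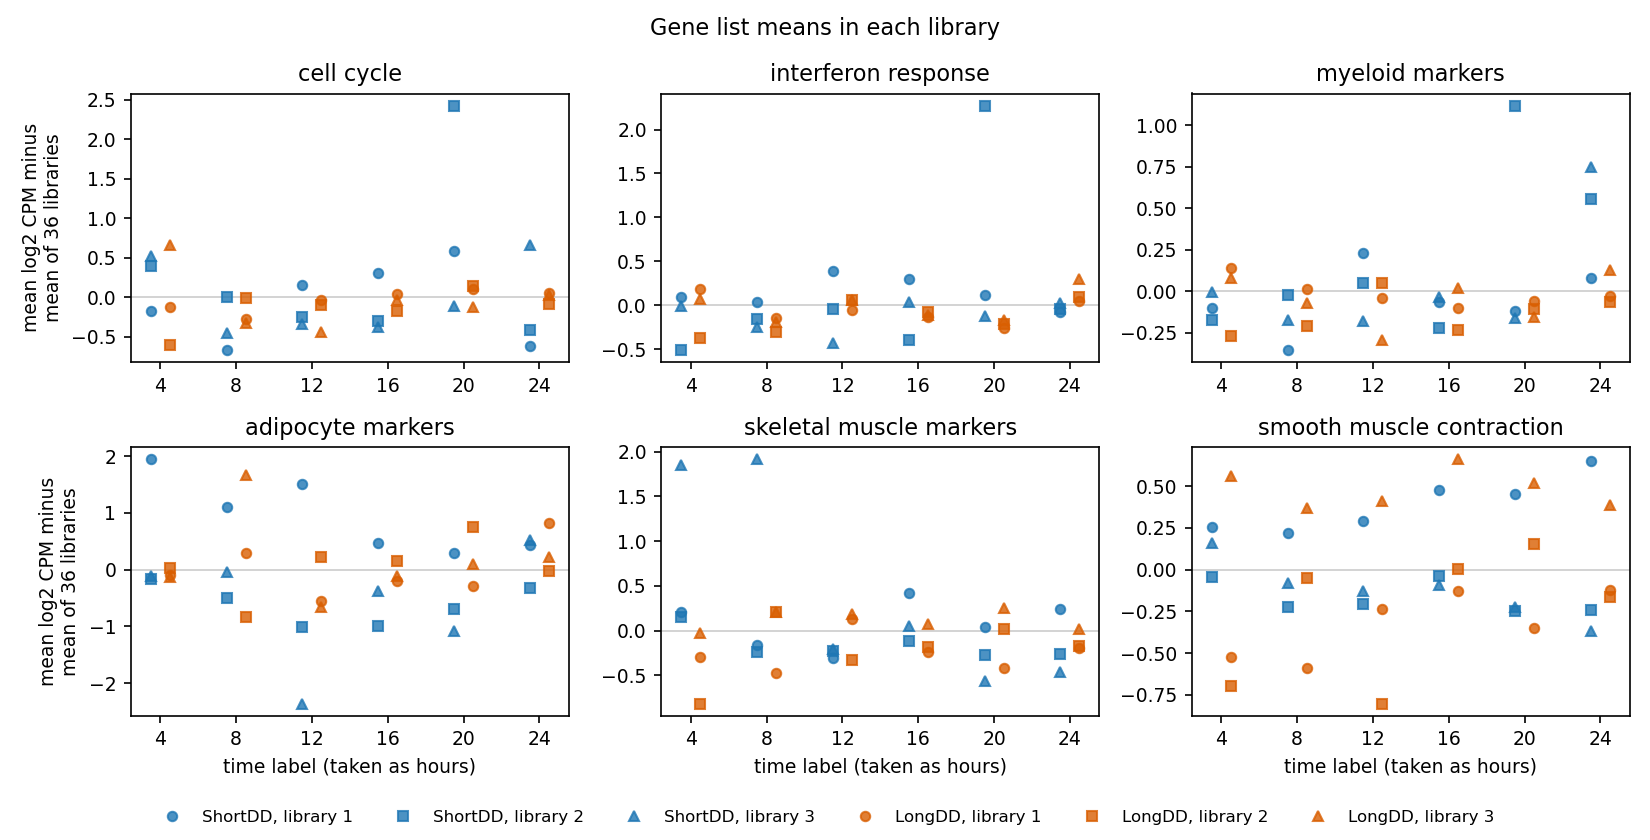
Mean log2 CPM of 6 gene lists in each library, minus the list's mean over the 36 libraries, by time label. Library 2 of ShortDD label 20 lies at 2.42 for cell cycle and 2.27 for interferon response.

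The second comparison asked the same of LongDD. Of the clock genes, Per2 and Arntl followed the label, and the others did not pass. Per2 had a range of 0.93 ± 0.20 (log2, SE, n = 18) with its peak at 9.1 h and Arntl a range of 0.82 ± 0.17 with its peak at 19.4 h, and both passed when adjusted over the core clock list alone (edgeR, adjusted p = 0.00249 each), though not with the time label as a factor. Nr1d1 had a range of 0.94 ± 0.39, Dbp 0.92 ± 0.46, Ciart 1.09 ± 0.52 and Nr1d2 0.34 ± 0.16, none of which passed. Other core clock members had ranges of 0.67 (Per3), 0.54 (Per1), 0.40 (Cry1), 0.26 (Npas2), 0.24 (Cry2), 0.18 (Clock) and 0.09 (Rora). In the clock output list 0 of 13 members passed when adjusted over the list alone, with ranges of 0.89 (Tsc22d3), 0.69 (Tspan4), 0.61 (Usp2), 0.56 (Coq10b), 0.51 (Tef), 0.47 (Bhlhe41), 0.36 (Hlf), 0.30 (Wee1), 0.26 (Bhlhe40), 0.22 (Nfil3) and 0.11 (Por), besides Dbp and Ciart. At an unadjusted p under 0.05 there were 4 of 12 core clock and 4 of 13 clock output members, more than among other genes (Fisher's exact test, adjusted p = 0.00417 each), at a threshold that was not fixed beforehand. T and B cell markers had 4 of 10 such members at that threshold (adjusted p = 0.00395), among them the immunoglobulin genes Jchain (range 2.40) and Ighm (2.06).

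Over all genes, 0 of 14552 passed in LongDD with edgeR (smallest adjusted p = 0.9996), and 451 genes (3.1%) had an unadjusted p under 0.05. DESeq2 called 2 genes (480 unadjusted), Per2 and Fmo2, the second of which falls outside the naming rule. limma-voom called 0 without quality weights (458 unadjusted) and 0 with them (1077 unadjusted). The unadjusted edgeR counts of both arms moved with the libraries. With the replicate number as a block they were 2317 in ShortDD and 1003 in LongDD. The LongDD count was 1339 of 14560 without the 6 LongDD libraries numbered 3. The ShortDD count was 1075 of 15063 without the 3 ShortDD libraries named above and 2617 of 14587 without the 6 numbered 1. None of the other 22 lists had a member that passed when adjusted over the list alone in LongDD (edgeR). Of genes tested in both arms, 87 had an unadjusted p under 0.05 in each, against 57.8 for independent sets (Fisher's exact test, p = 4.86e-05). That test takes genes as independent, whereas genes moved together with whole libraries, so its p can be far too small. The peaks of the 2 arms lay within 3 hours of one another in 34 of the 87 and within 6 hours in 53 (median difference -2.97 hours, LongDD minus ShortDD). Whether that is more than unrelated peaks would give was not tested. None passed in both after adjustment with edgeR, against 2 with DESeq2. Without library 3 of LongDD label 16, 12 clock genes passed when adjusted over their lists alone, in place of 2, and without the 6 LongDD libraries numbered 3 the count was 17.

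The third comparison tested the difference in rhythm itself. The 25 clock genes had a mean range of 1.04 in ShortDD (SD 0.68 over genes) and 0.53 in LongDD (SD 0.35), a difference of -0.50 on the log2 scale (permutation test of arm within time label, two-sided, p = 0.00359), and 23 of 25 genes had the smaller range in LongDD in the least squares fit of this test. In the edgeR fit, Tspan4 (0.47 in ShortDD, 0.69 in LongDD) and Tsc22d3 (0.75, 0.89) had wider ranges in LongDD, as had, by a small margin, Rora (0.07, 0.09) and Coq10b (0.55, 0.56). The largest gaps were those of Ciart (3.00 against 1.09), Dbp (2.40 against 0.92) and Nr1d1 (2.35 against 0.94).

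Gene by gene, 0 of 14858 genes passed the edgeR interaction test (smallest adjusted p = 0.181), and 1189 had an unadjusted p under 0.05. DESeq2 called 4 genes (1295 unadjusted), limma-voom 0 (1020 unadjusted) and limma-voom with quality weights 3 (1609 unadjusted). When adjusted over the list alone, the interaction passed for the REV-ERB genes Nr1d1 (edgeR, adjusted p = 0.00606) and Nr1d2 (0.0171) in the core clock list and for Nfil3 (0.0435), an antagonist of the PAR bZIP factors, in the clock output list. Nfil3 had a range of 1.29 in ShortDD and 0.22 in LongDD. The difference in mean range was -0.35 without the 6 LongDD libraries numbered 3 (permutation p = 0.0574) and -0.34 without the 3 ShortDD libraries named above (permutation p = 0.045).

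**Figure D3:**
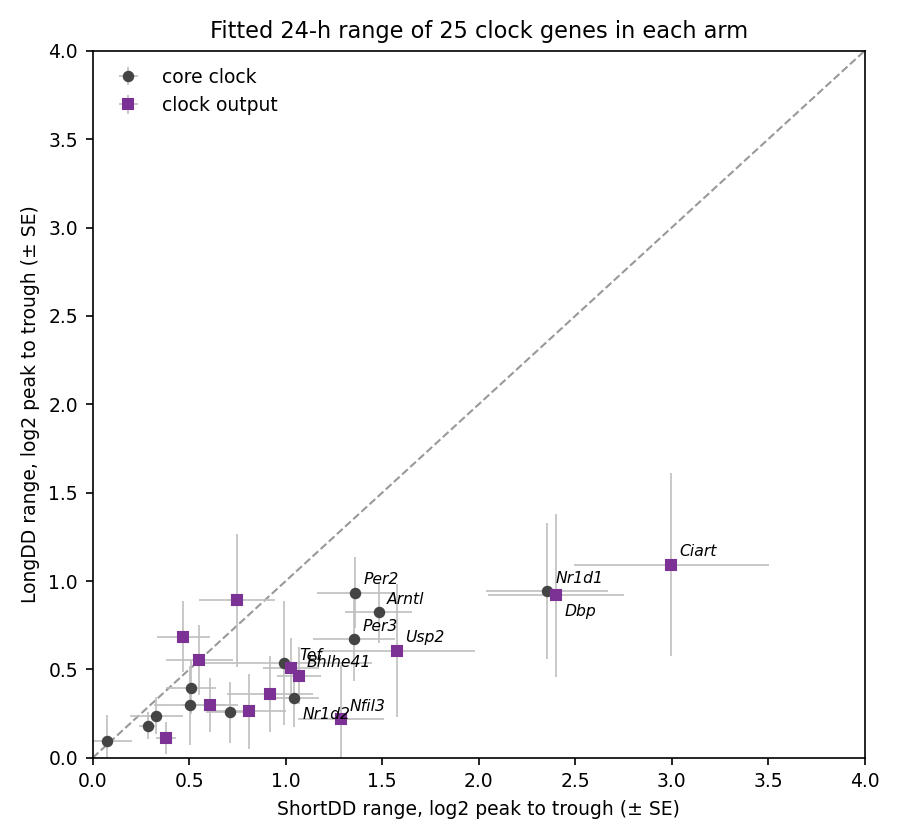
Fitted peak-to-trough range (log2) of 25 clock genes in ShortDD (x axis) and LongDD (y axis), with SE from the least squares fit. The dashed line marks equal ranges, and Dbp lies at 2.40 and 0.92.

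The fourth comparison asked which transcripts differed in mean level over the day. Dpt (chromosome 1, 164796644 to 164824266), a matrix gene of fibroblasts, was lower in LongDD by a log2 fold of -0.40 ± 0.06 (SE, n = 18 per arm), with a mean of 50.1 CPM against 66.8 CPM, and lay lower at 5 of 6 labels (edgeR, adjusted p = 0.00293). D3Ertd254e (chromosome 3, 36151017 to 36170342) was higher by 0.20 ± 0.03, with 43.6 CPM against 38.1 CPM, at 6 of 6 labels (edgeR, adjusted p = 0.00377). These were the 2 genes of 14858 that passed, with 565 higher and 678 lower at an unadjusted p under 0.05. DESeq2 called 12 higher and 12 lower, limma-voom 1 and 1, and limma-voom with quality weights 13 and 44. Neither passed without the 6 ShortDD libraries numbered 1 or at a fold of at least 1.5. Dpt did not pass with a time factor beside the arm. Over all 54 alternatives the folds stayed at -0.43 to -0.36 (Dpt) and 0.15 to 0.21 (D3Ertd254e). Of the clock genes none passed, over all genes or over the lists alone (edgeR), and their folds ran from -0.15 (Nfil3) to 0.37 (Ciart).

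Cholesterol synthesis genes were shifted upward in LongDD as a list, with 19 of 19 folds positive (median 0.11; camera at the preset correlation, adjusted p = 2.56e-06; adjusted p = 0.799 with an estimated correlation). In LongDD the mean of this list was 0.14 for the libraries numbered 1 and 2 and -0.10 for those numbered 3. The ShortDD means were -0.09, -0.02 and -0.08 for numbers 1, 2 and 3. Hmgcs1, which encodes a synthase early in the pathway, had a log2 fold of 0.21 ± 0.08, and no member passed on its own. Fibroblast and extracellular matrix genes were shifted downward, with 15 of 18 folds negative (median -0.18, adjusted p = 2.01e-05; adjusted p = 0.799 with an estimated correlation), among them the collagen gene Col3a1 (-0.34 ± 0.14) and Sparc (-0.31 ± 0.12). The LongDD means of that list were -0.26, -0.24 and 0.21 for numbers 1, 2 and 3, and the ShortDD means 0.04, 0.11 and 0.14. Myeloid markers were shifted downward with 15 of 15 folds negative (median -0.18, adjusted p = 8.49e-05; adjusted p = 0.799 with an estimated correlation), and the macrophage receptor gene Csf1r (-0.26 ± 0.06, lower at 6 of 6 labels) passed when adjusted over the list alone. The ShortDD side of that shift held the 3 libraries high in myeloid markers. Urothelium genes were shifted upward, with 16 of 21 folds positive (median 0.08, adjusted p = 0.0124; adjusted p = 0.892 with an estimated correlation), among them Shh (0.23 ± 0.08) and Trp63 (0.19 ± 0.08). The LongDD means of the urothelium list were 0.15, 0.08 and -0.14 for numbers 1, 2 and 3, and the ShortDD means -0.18, 0.10 and -0.01. Skeletal muscle markers were shifted downward, with 10 of 11 folds negative (median -0.27, adjusted p = 0.0454; adjusted p = 0.799 with an estimated correlation), in an arm comparison that includes the 2 ShortDD libraries high in those markers. None of the 24 lists passed with an estimated correlation or with fry.

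The other lists did not pass with camera at the preset correlation. Immediate early, cell cycle and interferon response genes had an adjusted p of 0.0637 each, with 11 of 17, 18 of 20 and 17 of 18 folds negative, and T and B cell markers 0.0969, with 12 of 12 negative. Library 2 of ShortDD label 20, which was high in the last 3 of these lists, lies on the ShortDD side of these folds. Clock output (0.148), core clock (0.171), endothelial markers (0.182), smooth muscle contraction (0.191), fatty acid and PPAR metabolism (0.33) and adipocyte markers (0.513) followed. Heat shock and cold-inducible, unfolded protein response, bladder sensing and contraction signalling, oxidative phosphorylation (nuclear), nerve and glia markers and female reproductive tract markers had 0.611, inflammatory 0.712, blood markers 0.763 and glucocorticoid response 0.938. Inflammatory and adipocyte markers had a negative median and mean with an upward test, fatty acid and PPAR metabolism a negative mean only, and glucocorticoid response a positive median and mean with a downward test.

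The libraries split on something other than their group. The 6 ShortDD libraries numbered 1 and the 6 LongDD libraries numbered 3 had higher means for smooth muscle contraction genes (0.39 ± 0.17 and 0.48 ± 0.12 on the log2 scale, SD, n = 6 each) than the other libraries, whose means by number ran from -0.33 to -0.12. Endothelial markers were also higher in both (0.17 and 0.41, against -0.18 to -0.09). For adipocyte markers only the ShortDD libraries numbered 1 had a high mean (0.96 ± 0.67, SD, n = 6, against -0.62 to 0.18 for the LongDD libraries numbered 3 and all others). Single libraries overlapped, with 0.30 to 1.945 in that set and up to 1.661 in LongDD number 3. In these 2 sets intron reads made up 21.7% to 31.0% and 20.7% to 28.7% of gene reads. The other libraries overlapped these ranges, with 24.1% to 38.8% in ShortDD and 26.5% to 35.4% in LongDD. Without the ShortDD libraries numbered 1, 0 genes passed in each direction with edgeR (533 higher and 482 lower unadjusted). Without the LongDD libraries numbered 3, 526 genes were higher and 742 lower, and without both sets 48 were higher and 86 lower.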

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

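The tests of phase scatter, of vector length and of the omission of sets of libraries in this part were chosen after the results they bear on were seen, except the count of genes with both sets of libraries left out, which was written down before its value was known.

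The clock genes differed between the arms in the mean size of their rhythm. Singly, Nr1d1, Nr1d2 and Nfil3 did from exon counts with adjustment over the list alone. Over all genes these 3 did not pass (edgeR interaction, adjusted p = 0.508, 0.607 and 0.607). The mean range of the 25 genes was lower in LongDD by -0.502 (log2, permutation test, p = 0.00359). The interaction passed when adjusted over the list alone for Nr1d1 (edgeR, adjusted p = 0.00606), Nr1d2 (0.0171) and Nfil3 (0.0435). Each library was also given a clock vector from the same genes, whose direction is an internal time and whose length is the size of the rhythm. The template was the ShortDD curves, fitted without the library itself. The mean resultant of the deviations from the label (1 when all agree) was 0.906 in ShortDD and 0.633 in LongDD, a difference of -0.273 (permutation p = 0.0138). It was -0.179 without library 3 of LongDD label 16 (permutation p = 0.0313), and the LongDD libraries numbered 1 and 2 had a resultant of 0.811 against 0.475 for those numbered 3. The ratio of mean lengths was 0.745 (permutation p = 0.0283). The internal time, set against the label, was ahead in LongDD by 2.1 hours on average (permutation p = 0.0412), where ahead means earlier peaks. That p was 0.05 or more in 17 of 36 omissions of a single library. The mean deviation from the label was 2.7 hours for the LongDD libraries numbered 1 and 2. For those numbered 3 it was -1.3 hours, so the lead did not hold for the whole arm. With the LongDD curves as template, the resultants were 0.909 in ShortDD and 0.591 in LongDD (permutation p = 0.0084). The ratio of mean lengths was then 0.723 (permutation p = 0.00693).

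For the smaller range of the clock genes in LongDD, 3 explanations were tested and none was excluded. Bladders out of phase with one another at a time label could be part of it, since the resultant was lower (-0.273). Some of that came through library 3 of label 16, which lay 9.1 hours from its label. Without that library the difference in resultant was -0.179 (permutation p = 0.0313). A smaller rhythm within each bladder could be another part, since the vectors were shorter (0.745), with the ShortDD curves, held fixed in the permutations, as template. The LongDD libraries numbered 3 could account for some of it, since without them the difference was -0.355 (permutation p = 0.0574) in a test with 6 fewer libraries. Without them and the ShortDD libraries numbered 1, which changes both arms, it was -0.477 (permutation p = 0.0104). How large that share is was not tested. The duration of darkness stays open as a biological explanation, untested, as no other genotype or lighting was part of the series.

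Cell cycle genes such as Tpx2 and Cdk1, interferon response genes such as Cxcl10 and Mx1, and myeloid markers such as Cd68 varied with the time label in ShortDD at an unadjusted p under 0.05, in 31 of 53 members. The 3 lists were put together after their values were seen. Without library 2 of label 20 and libraries 2 and 3 of label 24, which stood apart on principal components, the count was 0. These 3 libraries were high in myeloid markers, and that of label 20 in all 3 lists, so a fall was close to fixed in advance. The omission also took most of label 24, so it cannot tell single bladders that stood apart from a rise at labels 20 and 24. Over all genes the count at that threshold fell from 1905 of 14528 to 1075 of 15063. Blood markers (6 of 6, then 7 of 8) did not fall, and urothelium genes did (8, then 2). No biological explanation was tested, and what set the 3 bladders apart is open, RNA quality included, since the 2 of label 24 had the highest mitochondrial shares of all 36 libraries (1.65% and 1.59%), though that of label 20 had 1.14%.

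The number of genes that differed in mean level rose from 2 to 1268 without the 6 LongDD libraries numbered 3. Unequal tissue composition of the remaining libraries could account for most of it, since the count fell to 134 when the ShortDD libraries numbered 1, which shared their high smooth muscle contraction genes, were left out too, in a test with 6 fewer libraries. In LongDD the share of intron reads ran lower in number 3 (20.7% to 28.7%) than in numbers 1 and 2 (26.5% to 35.4%). In ShortDD the ranges overlapped widely, with 21.7% to 31.0% in number 1 and 24.1% to 38.8% in numbers 2 and 3. The labels do not say what the numbers stand for, so a batch, RNA quality, dissection and a difference between animals stay open. Whether the 134 genes are among the 1268 was not tested, and the duration of darkness stays open for them, untested.

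Intron reads, which the comparisons of the report did not use, carried a rhythm as well. From unique intron reads, 4 of 13694 genes passed in ShortDD with edgeR (1008 unadjusted), namely Arntl, Nr1d1, Nr1d2 and Dbp, all of which passed from exon counts too. In LongDD 0 of 13963 passed with edgeR (871 unadjusted), and 0 of 14368 differed in rhythm between the arms (946 unadjusted). Of 20 clock genes with enough intron reads, 12 passed in ShortDD, 1 in LongDD and 5 for the difference when adjusted over the list alone. For the mean level 1 of 14368 genes passed (928 unadjusted), namely the prostaglandin synthase gene Ptgs2, lower in LongDD by -1.34 (edgeR, adjusted p = 0.0493), whose fold from exon counts was 0.0045. Ptgs2 was named after its value was seen.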

How the results depend on the processing

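The alternatives that left out sets of libraries, nested the block in the arm or took other read counts as input were chosen after seeing the data. The others were fixed beforehand. Where no reason is given, the cause was not tested.

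Arntl, Bhlhe41, Dbp, Nr1d1, Nr1d2 and Tef passed in ShortDD in 36 of 36 alternatives. Fmo1 was lost without the 3 doubted libraries, Rnf144a without the ShortDD libraries numbered 1, and Per2 and Per3 in both. D3Ertd254e kept its call as higher in 53 of 54 and Dpt its call as lower in 52 of 54. These calls go by the adjusted p alone. They leave aside the minimum range and fold, which Rnf144a, D3Ertd254e and Dpt did not reach. Over the named genes, 4050 of 4240 ranges in ShortDD stayed on the same side of the adjusted p threshold, passing or not (162 lost their call, 28 gained one). So did 3841 of 3842 in LongDD, where no gene had passed in the report, and 2375 of 2424 folds (3 lost, 17 gained, 29 of the other sign).

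With DESeq2, 123 genes passed in ShortDD (18 of the 19 kept) and 2 in LongDD, 1 list was enriched in LongDD, 2 genes passed in both arms, 12 were higher and 12 lower, and 4 differed in rhythm. With sample quality weights, 14 clock genes passed over their lists alone in LongDD (2 in the report), 13 genes were higher and 44 lower, and 3 differed in rhythm. With library totals in place of TMM these clock genes were 6, and 8 lists (5 in the report) shifted in level.

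With an adjusted p under 0.01, 10 genes passed in ShortDD, by construction. With the time label as a factor 46 passed (12 of the 19 kept), with 0 clock genes over their lists alone in LongDD, and with the harmonic of period 12 there were 12. A range of at least 1 left 12 genes in ShortDD, 11 of 21 clock genes over their lists alone in ShortDD and 0 in LongDD, by construction. A time factor beside the arm left 0 genes lower, and a fold of at least 1.5 left 0 higher and 0 lower, by construction. No list shifted with camera at an estimated correlation (0) or with fry (0).

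With the replicate block, 20 genes passed in ShortDD and 1 in LongDD (Ttll7, named after its value was seen), and the clock range difference was -0.502 (permutation test, p = 0.0011). With the replicate block nested in the arm, 12 genes were higher and 18 lower. The numbers were not taken to pair the samples, since not every same-numbered pair correlated over 0.1. In ShortDD 9 of 15 pairs did for number 2 and 5 of 15 for number 3. In LongDD 9 of 15 did for number 1 and 7 of 15 for number 2. The 2 remaining sets were clearly grouped by number, with 14 of 15 pairs in ShortDD number 1 (mean r = 0.265) and 15 of 15 in LongDD number 3 (mean r = 0.384). Each library of these 2 sets correlated best with its own number. The main fits held no term for this grouping.

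Without the 3 doubted ShortDD libraries, 9 genes passed in ShortDD and 2 were lower (Dpt and Bmp1). Without the LongDD libraries numbered 3, 17 clock genes passed over their lists alone in LongDD, 526 genes were higher and 742 lower, and the clock range difference was -0.355. Without the ShortDD libraries numbered 1, 8 genes passed in ShortDD, 0 were higher and 0 lower, 1 differed in rhythm (Zfp420) and 12 lists shifted. Without both sets, 48 genes were higher, 86 lower and 11 lists shifted. Fewer libraries were tested in each.

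With each library left out in turn, 10 to 21 genes passed in ShortDD, with 10 without ShortDD 04 replicate 1, 11 without ShortDD 08 replicate 1 and 12 without ShortDD 04 replicate 3, 12 replicate 1 or 16 replicate 3. Clock genes over their lists alone were 21 to 23 in ShortDD and 2 to 12 in LongDD, with 12 without LongDD 16 replicate 3 and 4 without LongDD 24 replicate 3. Enriched lists were 2 to 3 in ShortDD. Genes were higher in 1 to 2 (Ppp2r2a added without LongDD 04 replicate 3) and lower in 1 to 2 (Bmp1 added without ShortDD 24 replicate 2). Shifted lists were 4 to 9, with 9 without ShortDD 16 or 20 replicate 3, LongDD 12 replicate 3 or LongDD 24 replicate 2, and 8 without ShortDD 04 replicate 1, 12 replicate 3, 16 replicate 2, 20 replicate 1 or 24 replicate 2, or LongDD 04 replicate 3, 08 replicate 1, 12 replicate 1, 16 replicate 1 or 16 replicate 2. The clock range difference was -0.583 to -0.396. The other counts stayed at 0.

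The 29 folds of the other sign were level folds of clock genes that did not pass for the level in the report. They were Per1 0.0082 (limma-voom); Per2 -0.0012, Arntl 0.0082 and Tsc22d3 -0.11 (quality weights). Without 1 library they were Per1 0.046 (ShortDD 04 replicate 1), 0.0094 (08 replicate 3), 0.11 (20 replicate 1) and 0.015 (LongDD 04 replicate 3), Rora 0.0035 (ShortDD 20 replicate 1), 0.015 (24 replicate 1), 0.0012 (LongDD 04 replicate 2) and 0.00036 (16 replicate 1), Hlf 0.021 (ShortDD 24 replicate 1) and Tsc22d3 -0.047 (LongDD 08 replicate 3). Over all single omissions the folds ran from -0.14 to 0.11 (Per1), -0.047 to 0.015 (Rora), -0.075 to 0.021 (Hlf) and -0.047 to 0.18 (Tsc22d3). Without the 3 doubted libraries it was Cry2 -0.030. Without the LongDD libraries numbered 3 they were Npas2 0.054, Clock -0.0029, Cry1 -0.038 and Tsc22d3 -0.20. Without the ShortDD libraries numbered 1 they were Arntl 0.0084, Usp2 0.085, Rora 0.085, Per1 0.22 and Hlf 0.12. Without both sets they were Clock -0.015, Arntl 0.038, Cry1 -0.0086, Per1 0.18 and Tsc22d3 -0.15. The cause was not tested.

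Small rhythms were often missed in the simulated data, where the share recovered at a range of 0.5 was 28.4% in ShortDD and 41.8% in LongDD. Those data held no differences shared by whole libraries. What depth limits was not tested.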

Other observations

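The tests in this part were fixed before their results were seen, and the genes of the first paragraph were chosen after their values were seen.

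Hemoglobin transcripts had wide fitted ranges in ShortDD, with 1.75 for Hbb-bs (peak at 1.3 h), 1.87 for Hbb-bt and 1.61 for Hba-a2, and narrow ones in LongDD (0.23, 0.11 and 0.36). The elastin gene Eln had a range of 1.31 in ShortDD (peak at 0.3 h) and 0.31 in LongDD. The antibody genes Jchain and Ighm went the other way, with 2.40 and 2.06 in LongDD against 0.98 and 0.63 in ShortDD. None of these genes passed over all genes in either arm (edgeR).

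The count of 19 genes with a rhythm in ShortDD was reached by 1 of 100 assignments of time labels, the real one itself. The highest other count was 1 gene. That argues against chance assignment for the count, but it does not test each of the 19 genes. A count of 0 is reached by every assignment, so these tests decide nothing for the 0 genes in LongDD (100 of 100, the highest other 1407) and the 0 genes with a different rhythm between arms (100 of 100, the highest other 627). A count of at least 1 gene higher was reached in 4 of 100 assignments of arm, the highest other with 18. At least 1 gene lower was reached in 3 of 100, the highest other with 12. Any gene was counted, and each direction apart, so D3Ertd254e and Dpt themselves were not tested. Both shares were under 0.05, but 100 assignments are too few to tell them from it. These assignments did not keep the grouping of the libraries by number, so they do not test that grouping. The 1 assignment of labels in LongDD and the 2 of arm that called more than 100 genes point to a structure of the samples other than their labels.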
